A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

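Ribosome profiling and RNA-seq were carried out on Saccharomyces cerevisiae BY4741, a haploid laboratory strain, grown in rich glucose medium (YPD) to mid-log phase. Per the labels, the RNA-seq library was made from cytoplasmically enriched RNA that was depleted of ribosomal RNA and fragmented by partial alkaline hydrolysis, with no poly(A) selection named. The footprint library was made from ribosome-protected mRNA fragments. There was 1 library per assay, so no value has a replicate error and no p-value is given across genes, which are not replicates.

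The deposited table gives 1 RPKM value per gene for each assay (reads normalized to gene length and library depth, computed by the authors per the file headers) and the log2 ratio of footprint to RNA RPKM, which the authors call the translational efficiency. The authors' deposited log2 column equalled the log2 ratio of the deposited RPKM columns for each gene, with a largest difference of 1.63e-09. Per the file headers, genes were kept if they had at least 10 RPM in the RNA-seq and more than 0 RPM in the footprints. The genome build named in the submitters' processing notes is sacCer3. The aligner, the counting rule, its use of strand, and the treatment of reads that match several genes are not given in the sources used here. A note deposited with the table says that each read begins with 8 random nucleotides that must be stripped. Genes outside the table are not analysed here, and nothing is said about their level.

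All 4685 identifiers in the table matched a locus tag of the NCBI reference annotation of assembly R64, the assembly that sacCer3 names, and took their symbol, coordinates and coding length from it. Gene models in that annotation hold no UTRs, so lengths are coding lengths. The table covers the 16 nuclear chromosomes and none of the mitochondrially encoded genes, and 1336 of the 6021 protein-coding genes of the annotation are not in it. RPKM multiplied by coding length summed to 908282 RPM for RNA and 968192 RPM for footprints, and all genes but 1 reached the stated minimum of 10 RPM computed in this way. RPKM values are printed to 2 decimals. Low footprint values fell on no recognisable series of whole reads: over 1670 trial step sizes for the 34 lowest genes, the best step exceeded chance by 0.284 of the genes it could test, and 155 of 200 sets of the same values shifted at random did as well. The coding length may differ from the length the authors used. Hence the depth of both libraries is unknown and no counting interval is given. Footprint values below 0.1 RPKM, which 11 genes have, carry a large rounding error.

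Ribosome density was computed as log2(footprint RPKM / RNA RPKM) with no pseudocount, for the 4642 genes whose mean of both RPKM values was at least 5, and was centred on the median of these genes, which had a footprint to RNA ratio of 0.821. A density of 1 therefore means 2 times as many footprints per unit length of mRNA as the median gene, not per mRNA molecule. Spread was measured as the SD over genes. Pearson and Spearman correlations are across genes. The slope of log2 footprint on log2 RNA was a reduced major axis. Intervals are the central 95% from resampling genes 2000 times (500 times for rank correlations), and they describe variation among genes, not between experiments. Codon adaptation was the geometric mean of relative codon weights, taken from the annotated cytosolic ribosomal protein genes with 0.5 added to each codon count.

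Before the data were examined, 31 gene lists, most of the alternatives and the rule for named genes were fixed. The others are marked as chosen after seeing the data. Each list with at least 4 measured members had its median density placed among the medians of 10000 random lists of the same size. These were matched in 20 bins on the mean of log2 RNA and log2 footprint. They were drawn from all analysed genes, the list's own members included. A list was said to stand apart when it lay outside the central 99% of those lists. This describes these libraries and is not a test of a condition. The named genes are the 10 highest and 10 lowest in density among genes with a mean RPKM of at least 20, the 5 highest in RNA and in footprints, the 2 highest and 2 lowest members of each list, all members of the lists for upstream open reading frames (uORFs), mating type, galactose and strain markers, HAC1, ABP140, EST3 and OAZ1, and the extreme subunits of 5 complexes. The value of 1 named gene is not reported here. Within complexes, the SD over subunits of log2 footprint was placed among random lists in the same way.

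The list test was tried on simulated densities over 4642 genes and lists of 20 genes. These were normal values drawn without regard to RNA level or coding length, with fewer random lists. Their spread came from the median absolute deviation of the real densities, not from the SD. Real densities went with RNA level and length, so the rates below need not hold for the real lists. The list test placed 39 of 40 lists raised by 1 (log2) and 10 of 40 lists raised by 0.5 outside the range, and 0 of 40 unshifted lists. For lists lowered by 1 the number was 39 of 40, and for lists lowered by 0.5 it was 10 of 40. The alternatives were no filter, a mean RPKM of at least 20, a pseudocount of 1, other centring, other matching, 1 gene per near-identical pair, adjustment for coding length by a lowess fit (fraction 0.3), partial rank correlations and other gene sets. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, Biopython 1.88, matplotlib 3.10.9 and RNAfold 2.7.2 were used.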

Results

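Steady-state mRNA and ribosome footprints were measured in exponentially growing BY4741 yeast, with 1 RNA-seq library and 1 ribosome footprint library. The series set out to describe what determines ribosome density in yeast. The comparison the design allows is therefore footprint against RNA for each gene, and then between genes. The table lists 4685 genes, of which 4642 passed the expression filter. The depth of the libraries is unknown, and differences between genes have no replicate check. Coordinates are those of assembly R64.

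The values were first set against the strain named in the labels. BY4741 is a MATa haploid in which LEU2, URA3 and MET17 are deleted and HIS3 is deleted in part, and those 3 fully deleted genes are not among the listed genes. HIS3, an enzyme of histidine synthesis, was listed with 97.2 RPKM of RNA and 138.5 RPKM of footprints. Of the 7 MATa-specific genes, 6 were listed. Their footprint values ran from 78.8 RPKM for STE6, the exporter of a-factor, to 1769 RPKM for MFA2, which encodes a-factor, with 1090 for MFA1, 315 for STE2, 229 for BAR1 and 158 for AGA2. Their densities relative to the median gene were -0.67 for STE6, -0.18 for STE2, 0.46 for BAR1, 0.69 for AGA2, 1.70 for MFA2 and 1.83 for MFA1. Of the 4 MATalpha-specific genes only the agglutinin gene SAG1 was listed, with 13.3 RPKM of RNA and 1.14 RPKM of footprints. Among the galactose genes, which glucose represses, the galactokinase gene GAL1 was listed at 8.48 RPKM of RNA and 0.03 RPKM of footprints. GAL80, the other listed member of that gene list, had 74.55 RPKM of RNA and 5.77 RPKM of footprints. Of the 29 meiosis and sporulation genes 2 were listed, both under the expression filter. RED1 had 8.64 RPKM of RNA and 0.09 RPKM of footprints, and ZIP1 had 6.05 and 1.83 RPKM.

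Genes with more mRNA had more footprints. The glycolytic and fermentation genes PDC1 (pyruvate decarboxylase), FBA1 (aldolase), GPM1 (phosphoglycerate mutase) and CDC19 (pyruvate kinase) had 4 of the 5 highest RNA values among the listed genes, at 17272, 13355, 10262 and 10041 RPKM. The ribosomal protein gene RPL39 was the fifth, at 9937 RPKM. PDC1 also led the listed genes in footprints with 22000 RPKM, followed by RPL39 with 20588, FBA1 with 17698, CDC19 with 15669 and the cell wall protein gene CCW12 with 15022. By RPKM times coding length, the 58 listed ribosomal protein genes took 10.7% of the listed RNA and 14.8% of the listed footprints. The 13 listed glycolysis and fermentation genes took 11.6% and 14.96%. TDH1, TDH2, TDH3, ENO1 and ENO2 of glycolysis and the elongation factor genes TEF1, TEF2, EFT1 and EFT2 are not among the listed genes, so these ranks and shares leave them out.

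Across the 4642 genes, log2 footprint and log2 RNA had a Pearson r of 0.92 (0.912 to 0.932 on resampling genes) and a Spearman rho of 0.92, so 85.1% of the variance of log2 footprint went with log2 RNA. The 1st to 99th percentiles spanned 333-fold in RNA, 3702-fold in footprints and 22.8-fold in density, and the 5th to 95th percentiles of density spanned 6.58-fold. The SD over genes was 1.61 for log2 RNA, 2.21 for log2 footprint and 0.96 for density. In all, 3721 genes (80.2%) lay within 2-fold of the median density, 315 (6.79%) above it and 606 (13.1%) below it. The low side had the longer tail, with 130 genes more than 4-fold below the median and 3 more than 4-fold above. These counts depend on the centring: against total footprint over total RNA, 26 genes were above 2-fold and 1646 below. The count of genes above 2-fold was 170 and that below was 349 among genes with a mean RPKM of at least 20.

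**Figure D1:**
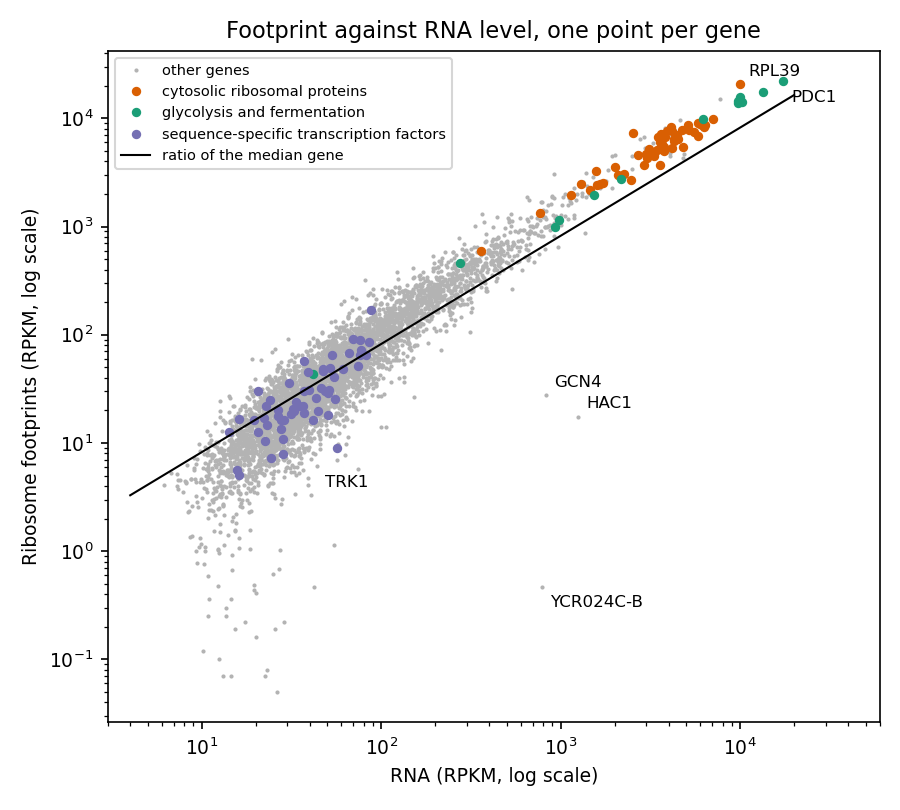
Footprint RPKM against RNA RPKM for 4642 genes, both on log scales, with 3 gene lists coloured and the line at the ratio of the median gene (0.821). The ribosomal protein and glycolysis genes shown lie above the line, and HAC1, GCN4 and YCR024C-B lie far below it.

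The lowest densities included HAC1 and GCN4, which are known for translational repression. HAC1, the transcription factor of the unfolded protein response, whose intron holds back its translation in unstressed cells, had 1246 RPKM of RNA and 17.5 RPKM of footprints, a density of -5.87 or 0.0171 of the median gene (chromosome VI, 75179 to 76147, with an intron inside the annotated gene, so that its coding length of 717 nt is that of the spliced form). GCN4, the activator of amino acid synthesis genes, whose leader carries inhibitory uORFs, had 830 RPKM of RNA and 27.7 RPKM of footprints, a density of -4.62 or 0.0407 of the median gene (chromosome V, 138918 to 139763). The lowest density belonged to YCR024C-B (chromosome III, 162599 to 162865), with 786 RPKM of RNA and 0.47 RPKM of footprints. Among genes with a mean RPKM of at least 20, the remaining members of the lowest 10 were YER186C (-6.21), YCL021W-A (-5.31), GAL80, the repressor of the galactose genes (-3.41), VMR1 (-3.32), TLD1 (-2.98), PPS1 (-2.76) and the dynein heavy chain gene DYN1 (-2.75). Among genes whose translation needs a ribosomal frameshift, ABP140 had a density of 0.83, EST3 0.02 and OAZ1, the ornithine decarboxylase antizyme, -0.73.

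The highest densities belonged to short genes. The top 10 had coding lengths of 204 to 696 nt and densities of 1.87 to 2.26. They were LSM3, a subunit of the Lsm ring that binds RNA (2.26), SPO24 (2.12), NCW1 (2.04), DPI8 (1.996), YDL012C (1.99), NOP16 (1.97), VPS24, a subunit of the ESCRT-III complex (1.94), CPP1 (1.92), the Hsp90 co-chaperone gene SBA1 (1.89) and the centrin gene CDC31 (1.87). LSM3, for instance, had 80.8 RPKM of RNA and 318 RPKM of footprints.

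Most of the 14 uORF genes lay below the median gene, but as a list they did not stand apart from random lists of like expression. The median density was -0.39 (-0.84 to -0.15), and 12 of 14 members were below the median gene. GCN4, PPR1 (-1.78) and the G1 cyclin gene CLN3 (-1.34) were more than 2-fold below it. HOL1 (-0.89), CPA1, whose uORF encodes the arginine attenuator peptide (-0.79), FOL1 (-0.57), HAP4 (-0.49), CAD1 (-0.29), SCH9 (-0.27), YAP1 (-0.25) and DCD1 (-0.15) were within 2-fold below the median gene, and INO2 (0.11) and SCO1 (0.50) were above it. The list's median lay at the 12.3rd percentile of random lists of like expression.

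Longer genes had lower density. The median density was 0.84, or 1.78 times the median gene, in the decile of shortest coding sequences (median 384 nt). It was -0.84, or 0.559 times the median gene, in the decile of longest (median 3606 nt), and each decile between lay below the one before it. The Spearman rho of density with coding length across genes was -0.62 (-0.637 to -0.600), and it was -0.60 given RNA level.

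Abundant mRNAs also had higher density. The median density was -0.68 in the decile of lowest RNA (median 14.7 RPKM) and 0.71 in the decile of highest (median 467 RPKM), and the Spearman rho was 0.53 (0.509 to 0.553). It was 0.51 given coding length and 0.38 among genes with a mean RPKM of at least 20. The reduced major axis slope of log2 footprint on log2 RNA was 1.37 (1.35 to 1.40), so footprints spread more widely than RNA. Density also went with codon adaptation, with a rho of 0.38 (0.358 to 0.410). Codon adaptation itself went with RNA at a rho of 0.63, and given RNA and coding length its relation with density was 0.26. The relation was not monotonic at its low end, since the decile of lowest codon adaptation had a median density of -0.09 and the next had -0.35.

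**Figure D2:**
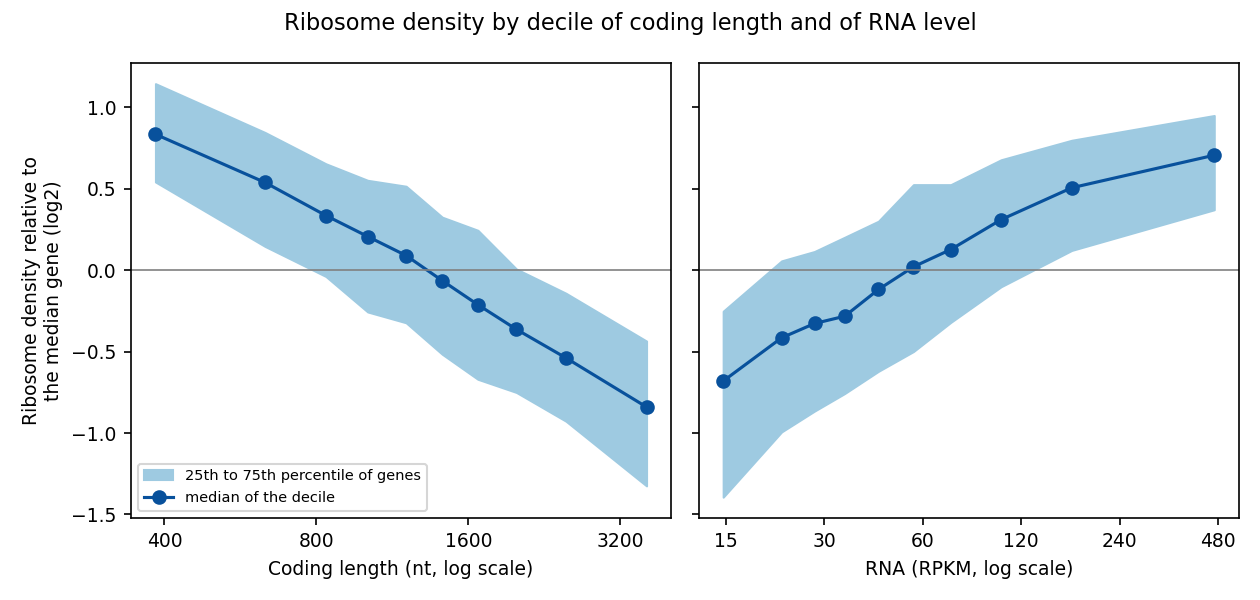
Median density relative to the median gene (log2) in each decile of coding length (left, nt) and RNA (right, RPKM), both on log scales, with the 25th to 75th percentiles of genes shaded. The median goes from 0.84 to -0.84 from the shortest to the longest decile, and from -0.68 to 0.71 from the lowest to the highest RNA decile.

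The mitochondrial lists and the stress list had the densities that stood highest against genes of like expression. The 32 nuclear-encoded subunits of the respiratory chain and ATP synthase had a median density of 1.01 (0.783 to 1.13), and 16 were more than 2-fold above the median gene. TIM11 (1.84) and QCR10 (1.76) were the highest, and ATP2, the catalytic beta subunit (0.00), and COX5B (0.11) the lowest. None of the 10000 random lists reached that median. The 76 genes of the mitochondrial ribosomal protein list had a median of 0.51 (0.402 to 0.598), which 5 of 10000 random lists reached. Their extremes were MRP35 (1.44) and KGD4 (1.43), and RSM22 (-0.62) and MRP1 (-0.51). KGD4, listed under its older name YMR31, is now annotated to the alpha-ketoglutarate dehydrogenase and not to the ribosome. The 14 listed general stress genes had a median of 0.78 (0.0639 to 1.10), which 42 random lists reached, with HOR7 (1.38) and YGP1 (1.31) highest and the trehalose synthase subunit TSL1 (-0.15) and the catalase CTT1 (-1.48) lowest. As measured, the stress list lay nearest of the 3 to the central range, at the 99.6th percentile. Among genes with a mean RPKM of at least 20 it no longer stood apart (99.3rd). With density adjusted for coding length, the respiratory chain list (0.29) and the mitochondrial ribosomal list (0.02) no longer stood apart, and the stress list (0.56) did. Among genes with at least 100 RPKM of RNA, a limit chosen after seeing the data, only the respiratory chain list of the 3 still stood apart, and 7 members were left in each of the other 2.

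The lists of the translation machinery had medians above the median gene, though as measured none stood above random lists of like expression. All 58 listed cytosolic ribosomal protein genes lay above the median gene, with a median of 0.86 (0.808 to 0.951), and 20 were more than 2-fold above. RPS29A (1.81) and RPS28B (1.34) were the highest, and RPS1B (0.34) and RPS1A (0.41) the lowest. Their median was at the 78.5th percentile of random lists of like expression, which could include these same genes. The place depended on the comparison. It was the 95.95th against lists matched on RNA alone and the 48.0th among genes with a mean RPKM of at least 20. Among genes with at least 100 RPKM of RNA it was the 32.9th. Given their short length the same genes stood low: with adjustment for coding length the median was 0.17, below each of the 10000 random lists. Of the 137 ribosomal protein genes in the annotation 79 are not listed, and nearly all of these belong to A and B pairs of near-identical copies. Values of listed copies such as RPS1A and RPS1B are uncertain where reads could be shared. Initiation factors (25 genes) had a median of 0.54, from the eIF3 subunit gene HCR1 (1.22) and TIF5 (0.96) to the eIF2B subunit genes GCD6 (-0.31) and GCD1 (-0.28). The 5 listed elongation factors had a median of 0.68, from HYP2, which encodes eIF5A (1.37), and EFB1 (0.995) to TEF4 (0.53) and YEF3 (0.12). The 41 ribosome biogenesis genes had a median of 0.57 and lay within the central range as measured and above it after adjustment for length (0.58), with GAR1 (1.74) and MAK16 (1.59) highest in measured density and UTP20 (-1.44) and UTP10 (-1.02) lowest. The 20 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, had a median of 0.39 (0.241 to 0.535). That was lower than all but 2 of the 10000 random lists of like expression, with DPS1 (0.82) and FRS2 (0.81) highest and VAS1 (-0.15) and ILS1 (-0.30) lowest. Adjusted for length, the synthetases' median was 0.72, at the 99.1st percentile and so within the central range. Against random lists matched on RNA alone they lay at percentile 0.51, just inside the limit of 0.5.

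The central metabolism lists had medians above the median gene too, and as measured they did not stand apart from random lists of like expression. Glycolysis and fermentation (13 genes) had a median of 0.69, from the hexokinase gene HXK1 (1.02) and the triosephosphate isomerase gene TPI1 (0.96) to PFK2 (0.38) and PYK2 (0.33), and all 13 were above the median gene. The 16 genes of the TCA cycle had a median of 0.62, from SDH4 (1.06) and LSC1 (0.81) to CIT2 (0.07) and KGD1 (-0.07). Amino acid biosynthesis (41 genes) had a median of 0.45, with LYS1 (1.198) and HOM2 (1.10) high and SER3 (-1.32) and ARG8 (-1.41) low. Ergosterol biosynthesis (24 genes) had a median of 0.50, with IDI1 (1.11) and ERG20 (0.85) high and both HMG-CoA reductase genes, HMG2 (-0.70) and HMG1 (-0.70), low. After adjustment for length, the TCA cycle and amino acid lists stood above random lists, with medians of 0.59 and 0.57. The cell wall list (20 genes) had the second highest median of the tested lists, 0.96 (0.603 to 1.15), with CCW14 (1.83) and CIS3 (1.80) high and UTR2 (0.22) and SUN4 (0.19) low. It lay at the 98.7th percentile, inside the central range, and outside it with random lists matched on RNA alone (99.8th).

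Most listed chaperone genes lay above the median gene as well. The 18 listed chaperone genes had a median of 0.76, from the Hsp40 gene SIS1 (1.41) and the cyclophilin gene CPR1 (1.15) to KAR2 (-0.16) and the stress-induced Hsp70 gene SSA3, which had 20.1 RPKM of RNA, 0.41 RPKM of footprints and a density of -5.33. The list lay within the central range as measured and above it after length adjustment (0.75).

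The lists of regulators and membrane transporters had medians below the median gene, with members on both sides of it. Those above it were 20 of 57 transcription factor genes and 7 of 28 cell cycle regulators. Of the others, 10 of 24 transporters and 16 of 37 replication and repair genes lay above it. The 57 transcription factor genes had a median of -0.22 (-0.432 to -0.0128), with GCR1, an activator of glycolytic genes (-2.38), and PDR3 (-1.56) lowest and CBF1 (1.23) and HAP3 (0.89) highest; 8 were more than 2-fold below the median gene and 1 above. The 28 cell cycle regulators had a median of -0.30 (-0.489 to -0.121), from the separase gene ESP1 (-2.12) and the kinase gene SWE1 (-1.78) to PDS1, the inhibitor of separase (1.07), and CKS1 (0.90). The 24 nutrient transporters had a median of -0.19 (-0.368 to 0.13). The potassium transporter gene TRK1 (-2.56) and PHO87 (-1.80) were lowest and the hexose transporter genes HXT1 (0.69) and HXT2 (0.56) highest. HXT3, HXT4, HXT5, HXT6 and HXT7 are not among the listed genes. DNA replication and repair (37 genes) had a median of -0.07, from POL30, which encodes PCNA (1.05), and RFA2 (0.995) to RAD54 (-0.80) and POL2, the catalytic subunit of DNA polymerase epsilon (-0.97). None of these 4 lists lay outside the central range. The transporters came nearest to its edge, at percentile 0.89 against the limit of 0.5. Adjusted for length, the medians were -0.02 for transcription factors, -0.08 for cell cycle regulators and 0.08 for transporters. DNA replication and repair then stood higher than random lists (0.37). The 3 listed histone genes, too few for the list test, were HTB1 (1.35), HTB2 (1.29) and HTZ1 (0.73), and HTB1 and HTB2 are near-identical copies.

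**Figure D3:**
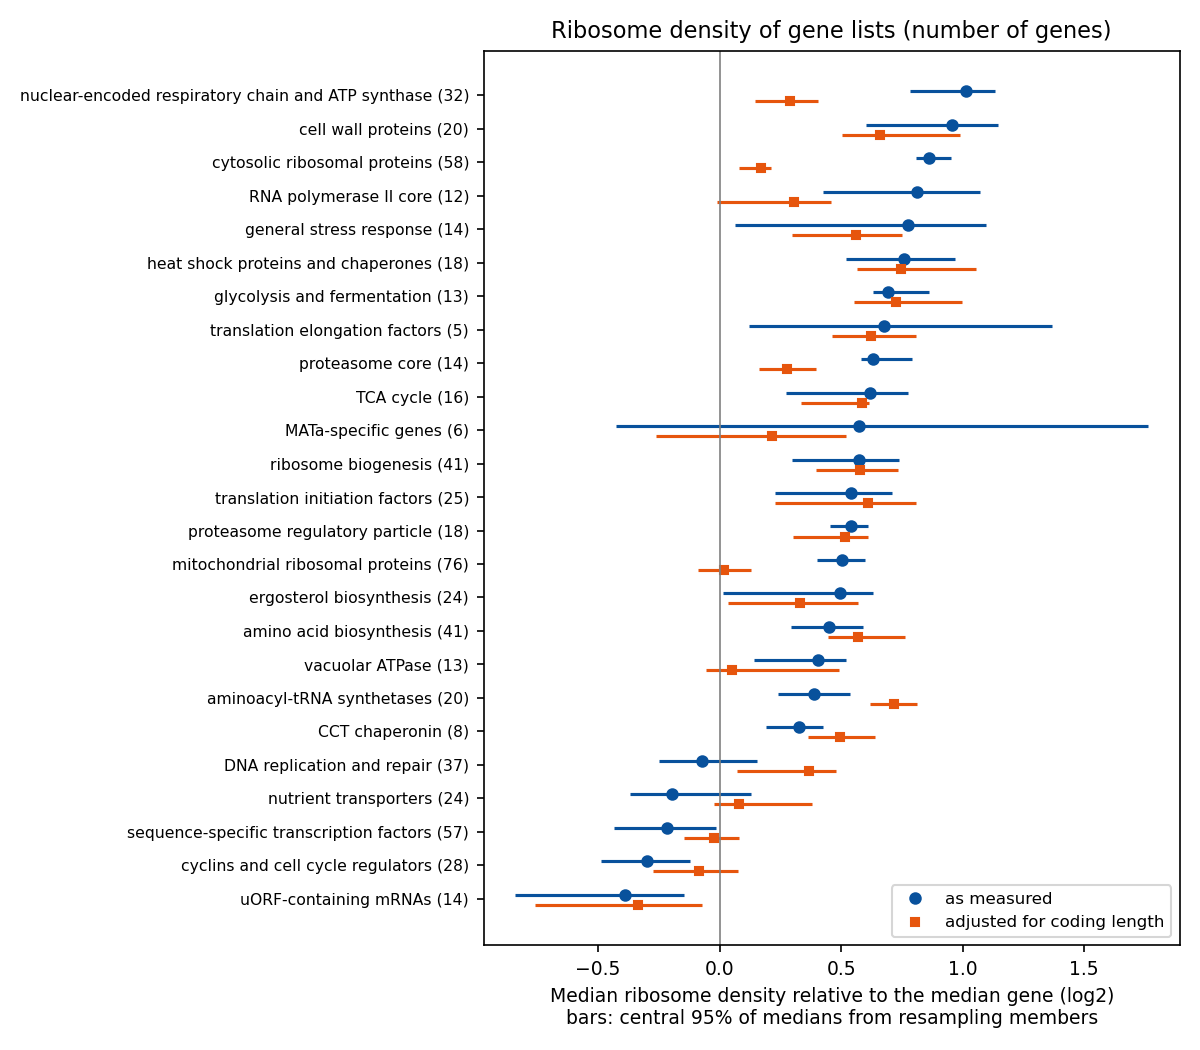
Median density relative to the median gene (log2) of the 25 tested gene lists, as measured (circles) and adjusted for coding length (squares), with bars for the central 95% of medians from resampling members and the number of genes in parentheses. The respiratory chain list has the highest measured median, 1.01, and the uORF list the lowest, -0.39; adjustment takes the ribosomal protein list from 0.86 to 0.17.

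Subunits of 2 complexes had nearly even footprint levels, a measure of synthesis rate if elongation is alike. The 14 genes of the proteasome core, the barrel that degrades proteins, had footprint values from 254 RPKM (PRE5) to 397 RPKM (PRE9), a 1.56-fold range with an SD of 0.18 (log2); none of 10000 random lists of like expression was as narrow. The densities of PRE7 (0.82), PRE3 (0.82), PRE10 (0.52) and PRE5 (0.31) span the complex. The 8 genes of the CCT chaperonin, which folds actin and tubulin, ran from 223 RPKM (CCT7) to 318 RPKM (CCT5), an SD of 0.20 that 19 random lists matched or undercut. CCT3 (0.50) and CCT7 (0.47) had the highest densities there and CCT5 (0.18) and CCT4 (0.12) the lowest. The SD was 0.19 for RNA and 0.18 for footprints in the proteasome core, and 0.26 and 0.20 in CCT. With the interquartile range in place of the SD, CCT no longer stood apart, at the 5.36th percentile.

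The other complexes had wider spreads by SD. By interquartile range, the proteasome regulatory particle (0.27) was narrower than CCT (0.31). The 18 genes of the proteasome regulatory particle ran from 145 RPKM (RPN9) to 293 RPKM (RPT1), an SD of 0.26 at the 8.21st percentile. Matching the random lists on footprint as well as RNA narrows them; matched on RNA alone, which was chosen after seeing the data, none of 10000 lists was as narrow as the regulatory particle. Their densities went from 1.02 for RPN13 and 0.98 for RPN11 to 0.03 for RPN2 and 0.02 for RPN3. The 13 genes of the vacuolar ATPase, the proton pump of the vacuole, ran from 272 RPKM (VPH1) to 2002 RPKM (VMA10), a 7.35-fold range with an SD of 1.06 at the 18.2nd percentile. Its subunits are not all present in equal number. VMA4 (1.40) and VMA10 (1.21) had the highest densities and VMA5 (0.07) and VPH1 (-0.21) the lowest. The 12 genes of RNA polymerase II, some of which also serve RNA polymerases I and III, ran from 112 RPKM (RPB7) to 586 RPKM (RPC10), an SD of 0.88 at the 85.3rd percentile. The large subunit genes RPO21 and RPB2 had densities of -0.53 and -0.57, against 1.501 for RPC10 and 1.27 for RPB9.

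**Figure D4:**
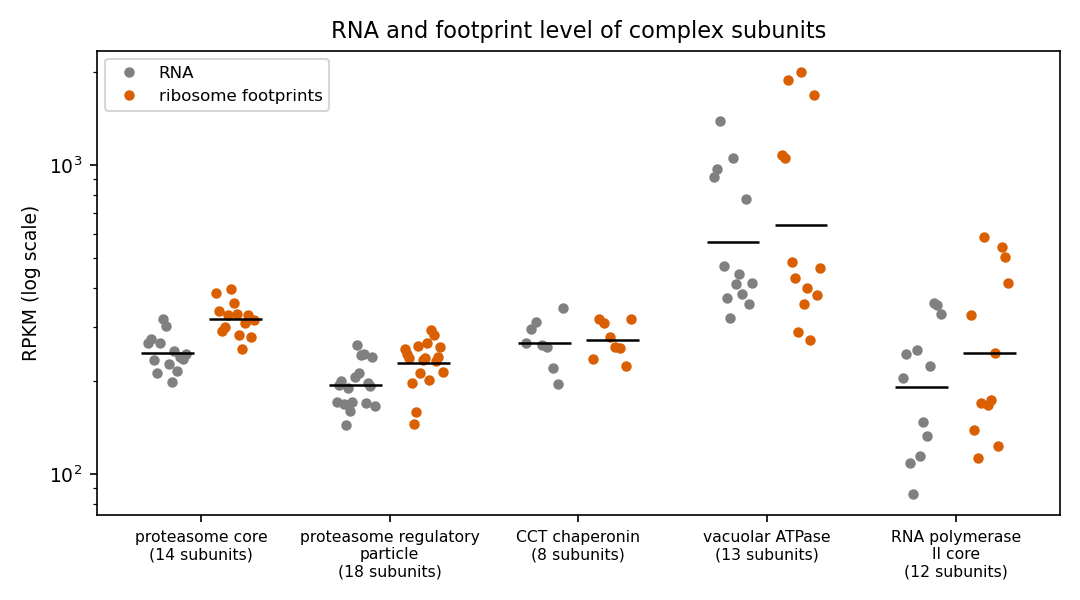
RNA and footprint RPKM (log scale) of the subunits of 5 complexes, 1 point per gene, with lines at the geometric means. The proteasome core spans 1.56-fold in footprints and the vacuolar ATPase 7.35-fold.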

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

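No paired analysis was possible because each assay has 1 library, so no replicate could be left out either. A value was taken to have moved when it shifted by more than its resampling interval reaches, on average, to either side, or a count by more than 1.5 times. The direction of each correlation and slope was the same under each alternative. Without the expression filter, the SD of density was 1.02 and the slope 1.40. With a pseudocount of 1, the SD was 0.83, the correlation 0.94 and the slope 1.33. Requiring a mean RPKM of at least 20 gave an SD of 0.75, a slope of 1.26, 170 genes above and 349 below 2-fold, a rho of 0.38 with RNA and of -0.64 with coding length. That filter raised the median gene by 0.18, and with it the medians were 0.68 for ribosomal proteins, 0.21 for tRNA synthetases, 0.51 for glycolysis, 0.83 for the respiratory chain, 0.32 for mitochondrial ribosomal proteins, 0.45 for the proteasome core, 0.36 for the regulatory particle, 0.15 for CCT and 0.27 for amino acid biosynthesis. Centred on total footprint over total RNA, 26 genes were above and 1646 below 2-fold. Without ribosomal protein and glycolysis genes the correlation was 0.91, and least squares gave a slope of 1.27. The rho of density with abundance was 0.70 with the mean of both assays as abundance and, chosen after seeing the data, 0.51 given coding length. The rho with codon adaptation was 0.26 given RNA and length. Of 25 lists, 3 stood higher and 1 lower. With random lists not matched, 14 stood higher and 0 lower. Matched on RNA alone, 0 stood lower, with tRNA synthetases just inside the limit at percentile 0.51. Adjusted for coding length, 6 stood higher, of which 1 was among the original 3, and 2 stood lower, ribosomal proteins and the vacuolar ATPase. Their medians then were 0.17 for ribosomal proteins, 0.72 for tRNA synthetases, 0.29 for the respiratory chain, 0.0175 for mitochondrial ribosomal proteins, 0.28 for the proteasome core, 0.051 for the vacuolar ATPase, 0.50 for CCT, 0.30 for RNA polymerase II, 0.66 for cell wall proteins, 0.0784 for nutrient transporters, -0.0845 for cell cycle regulators and 0.37 for DNA replication. Chosen after seeing the data, a minimum of 100 RPKM of RNA left 22 lists, of which 1 stood higher and 2 lower, with medians of 0.23 for nutrient transporters and 0.80 for DNA replication, since fewer members remained. The respiratory chain stayed higher and tRNA synthetases lower, the vacuolar ATPase became lower, and mitochondrial ribosomal proteins (52.1st percentile) and general stress genes (94.7th), with 7 members left in each, no longer stood apart. These medians keep the centring of the main analysis. The 100 RPKM alternative was first run recentred on its own 1200 genes, and the version with the main centring was chosen after that outcome had been seen. Recentring leaves percentiles and calls as they are but takes 0.54 (log2) off each median: 17 of 22 medians then moved and 2 reversed, tRNA synthetases to -0.15 and mitochondrial ribosomal proteins to -0.0854. Both remain values relative to a more abundant median gene. The other medians that moved were 0.32 for ribosomal proteins, 0.0356 for initiation factors, 0.0696 for ribosome biogenesis, 0.18 for glycolysis, 0.0763 for the TCA cycle, 0.40 for the respiratory chain, 0.0882 for the proteasome core, -0.00282 for the regulatory particle, -0.14 for the vacuolar ATPase, -0.22 for CCT, 0.26 for RNA polymerase II, 0.26 for heat shock proteins, 0.25 for general stress genes, -0.11 for amino acid biosynthesis, 0.00647 for ergosterol biosynthesis, 0.41 for cell wall proteins and 0.25 for DNA replication. With a mean RPKM of at least 20, 2 lists stood higher, and the general stress list no longer did (99.3rd percentile). With the interquartile range, 1 complex stood apart in place of 2. With random lists matched on RNA alone, chosen after seeing the data, 3 did, the third being the proteasome regulatory particle. Beyond the construction named for each, the cause was not tested. The depth of both libraries is unknown, and the authors' minimum of 10 RPM keeps short genes of low RNA out of the table.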

Other observations

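Of the tests below, those of errors in the RNA values, of a fixed number of extra footprints, of RNA level alone, of coding length alone and of background RNA were set up after values that decide or bear on them had been seen (rank correlations, deciles and the lowest genes). The others, including the limit of 100 RPKM, were chosen after the patterns had been seen but before their own results. Most ribosomal protein genes come in pairs named A and B, many of them near-identical copies, and 16 pairs had both copies listed. Pairs were taken by name, RPP1A with RPP1B and RPP2A with RPP2B included. Copies differed more in RNA than in density: 8 pairs were more than 2-fold apart in RNA, and none was in density. RPL22A had 4176 RPKM of RNA and RPL22B 362, with densities of 1.17 and 1.01. RPS22A had 3818 and RPS22B 770, with densities of 1.11 and 1.08. The widest gap in density was between RPS28A (0.64) and RPS28B (1.34). The median difference within pairs was 0.12 (log2), against 0.22 when the same genes were paired at random, and 143 of 10000 random pairings were as close. Copies have the same or similar coding lengths, and reads that match both could also have been shared between them, so these values are uncertain.

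Lower density in longer genes was weighed first. The authors' RPM minimum removes short genes of low RNA, but among the 1200 genes with at least 100 RPKM of RNA, a level that each length can reach, the rho with coding length was -0.64 (-0.683 to -0.604). A fixed number of extra footprints per reading frame, such as ribosomes held at start and stop codons, was fitted on the shorter genes and came to the equivalent of 410 nt. The drop it predicts over the longer genes is 0.17 (log2), and the observed drop was 0.63, which is 3.76 times as large (2.97 to 4.62). RNA level alone does not account for it either, with a partial rank correlation of -0.60 given RNA. A lower initiation rate, ribosomes lost along the reading frame and unequal recovery of long mRNAs remain open and untested, since gene totals do not separate them. The sequence tests at the end use density adjusted for coding length, so they do not address the fall with length.

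Higher density in abundant mRNAs was weighed second. Errors in the RNA values enter the ratio with the opposite sign and would give a negative relation, and the observed rho was 0.53. Coding length alone would leave no relation once length is held, and the partial rank correlation was 0.51 (0.483 to 0.527). Shared sequence properties, such as codon usage, remain open. So does a low background of RNA reads, which would lower density most where RNA is low and was not tested for this pattern. The rho was 0.38 among genes with a mean RPKM of at least 20. Below 20 RPKM of RNA, that limit keeps only genes with more footprint than RNA. The lower rho may thus be built in, and it does not bear on background.

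The third pattern is 30 genes with RNA but a density more than 16-fold below the median gene. Apart from HAC1 and GCN4, these genes had at most 1.13 RPKM of footprints. With the depth unknown, ratios that rest on such low footprint values are uncertain in size. None of the 30 genes overlaps another annotated gene (0%, with a Wilson 95% upper limit of 11.4%). The share was 1.40% of the genes analysed and 16.01% of the protein-coding genes outside the table. Such overlap is rare among the genes analysed, and the annotation holds no UTRs, so overlap of transcripts was not examined. The neighbours of the 30 genes were not unusually abundant: the median log2 ratio of adjacent to own RNA, over the 24 with a listed neighbour, was 1.86, at the 51.3rd percentile of random lists matched on RNA. A low background of RNA reads may contribute to some, since 13.3% of them (5.31% to 29.7%) had more RNA than the median gene, which neither excludes nor bears out such a background for the set. Of the 4 genes above that level, HAC1 (1246 RPKM of RNA), GCN4 (830) and YCR024C-B (786) lie too far above it for a low background to account for their RNA. YCL021W-A, with 54.6 RPKM against 49.6 for the median gene, lies just above it, so background is not excluded there.

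YCR024C-B, chosen after its values were seen, lies on the minus strand 79 nt from PMP1 (chromosome III, 162945 to 163067), a short plasma membrane protein gene on the same strand with 2004 RPKM of RNA and 4581 RPKM of footprints. YCR024C-B lies on the 3' side of PMP1. Whether the 786 RPKM of RNA counted there belongs to the end of PMP1 transcripts was not tested, as no transcript ends are in the annotation used.

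Sequence around the start codon was tested as a further correlate, with density adjusted for coding length and RNA, which together took up 40.2% of its variance. Genes with A at the position 3 nt before the start codon (2850 of 4642) had a median adjusted density higher by 0.101 (0.063 to 0.129) than the other 1792, which lies barely above the 0.1 set beforehand, with an interval that reaches below it, so this support is marginal. Genes with an ATG within 50 nt before the start codon (819) had a median that differed from that of the others by -0.22 (-0.267 to -0.176), so it was lower. The difference passed the limit set beforehand, but that limit lies within the interval. Predicted folding free energy of the 50 nt before and 20 nt after the first base of the start codon had a partial rank correlation of 0.23 (0.202 to 0.254) with density, so weaker predicted folding went with higher density. The last is consistent with start-proximal structure and density being linked, but transcription start sites are not in the annotation, so part of each 50 nt may lie outside the mRNA, and the effects are small beside the SD of 0.96 over genes.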
